A study of Mus musculus with 6 samples.

How the data were processed

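RNA from aortic arteries of C57BL/6 mouse fetuses was hybridised to 1-colour Cy3 Agilent expression arrays. Per the labels, Nod1 -/- dams had been mated with Nod1 +/- males and injected subcutaneously with 500 µg of FK565, a synthetic ligand of NOD1, at embryonic day 18.5, and fetal vessels were taken 6 h later. Arrays were grouped by the genotype in their labels, with 3 Nod1 +/- and 3 Nod1 -/- arrays. The design text calls the fetuses littermates. Whether each array held a single fetus was not stated, so p-values measure the spread between these samples. The number of arrays limits the precision.

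The deposited scanner output gives each spot as an intensity on a linear scale, background-subtracted by Agilent Feature Extraction 10.7.1.1, per the file headers. The submitters' processing notes name version 9.5.1.1 of the same program, and the disagreement was not resolved. Per the file headers, probe positions refer to mm9 and all 6 arrays lay on 1 slide with 1 scan time. The files place Nod1 -/- replicates 1 and 2 in row 1 of the slide and the other 4 arrays in row 2. The deposited value table of the whole series, also an intensity table by the authors, had a median of 33.4 in every column, and 0 of its columns lacked a sample. The step that gave its columns equal medians was not stated in the sources used here, so this table served only as an alternative.

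Control spots and spots marked as outliers by the scanner software were left out, and no spot was saturated. Processed signals were taken to log2, spots of the same probe were averaged, and the array's 75th percentile over non-control probes was subtracted. Of 55681 non-control probes, 134 lacked a usable spot on some array and were left out. A probe was kept when it was well above background on at least 3 of the 6 arrays, whatever the genotype, which left 30166 probes. A gene was represented by its kept probe with the highest mean, giving 21478 tested genes. Among 5990 genes with several kept probes, 1084 changed, and 7 of these had another probe past the threshold in the other direction. Gene names were those of the array design. Of its 34797 distinct names, 19985 matched a current symbol in the RefSeq gene table given, 373 a synonym and 2030 an accession, and 12409 matched none and kept the name in the file. No coordinates were taken from that table, because its assembly was not mm9. Exons of mm9 were not used here, so a probe's place within its gene is not given.

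Genotypes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as Nod1 +/- minus Nod1 -/-, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Text was read with fread of R's data.table package (version 1.17.8) and plots drawn with matplotlib 3.10.9 and numpy 2.4.6. Shifts of gene lists were tested with camera at a preset correlation of 0.01, adjusted over 31 lists. A pair of further lists, of sex-linked genes and of genes near Nod1, served as checks. For a gene not well above background on any array of a genotype, only a bound is given as "at least N-fold". It sets the brighter genotype's mean against the dimmer genotype's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

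The design, the gene lists, the processing alternatives and the rule for naming genes were fixed before the data were examined. The rule took Nod1, then the 10 largest differences in favour of Nod1 +/- and the 8 largest in favour of Nod1 -/-, among changed genes whose genotypes did not overlap, which were well above background on all arrays of the brighter genotype and which had a gene symbol. From each list it added up to 4 changed members with the smallest p, or values of up to 2 members where none had changed. Genes outside this rule are said to be so where they are named.

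Alternatives covered the background correction (normexp with an offset of 50), quantile and median scaling, filters on dim probes, and every probe or the mean of a gene's probes. They also covered an intensity trend with a robust prior, array weights, the replicate number or the slide row as a block, Xist signal as a covariate, the deposited value table, a 2-fold minimum, camera with an estimated correlation and fry. Each array was left out in turn. A fit without the first replicate of both genotypes was added after the data had been seen.

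The test was tested on simulated data with the means and spreads of these 21478 genes, in 10 runs. Differences of 2 on the log2 scale were recovered in 79.9% of genes, of 1 in 44.8% and of 0.5 in 1.9%. There were 1 to 11 false calls per run, a mean of 4.1% of calls. A list shifted by 1 was called in all 10 runs, with 1 call of another list. Simulated genes were drawn independently, so the runs do not test the preset correlation on lists whose genes vary together. In the data the estimated correlation reached 0.859 for skeletal-muscle genes. Over the 10 runs 699, 663 and 638 genes were changed by 0.5, 1 and 2. That is far fewer per run than were called in the data, so the recovered shares need not hold there.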

Results

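Gene expression was measured in aortic arteries of Nod1 +/- and Nod1 -/- fetuses from dams given FK565, to examine how the fetal vascular system responds to a NOD1 ligand in vivo. NOD1 is a cytosolic sensor of bacterial peptidoglycan fragments that signals through RIPK2 to NF-kB. There were 3 arrays per genotype and none from dams without the ligand. Signal was well above background for 48.6%, 52.6% and 54.7% of probes on Nod1 +/- replicates 1 to 3, and for 58.3%, 56.5% and 53.7% on Nod1 -/- replicates 1 to 3. The 75th percentile of signal lay between 434.8 and 514.3. Values below are log2 signal minus that percentile, means are given with SD (n = 3), and differences with their standard error and limma's adjusted p.

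The targeted gene was read by 1 probe, on chromosome 6 at 54874007 to 54874066 of mm9, minus strand. Nod1 lay at 3.38 ± 0.35 in Nod1 +/- and 3.25 ± 0.09 in Nod1 -/- aortas, a difference of 0.13 (95% confidence interval -0.32 to 0.59; adjusted p = 0.648). The sources used here do not say which part of Nod1 was deleted, so the probe may lie outside it and does not check the labels. Sex-linked probes varied within both genotypes. Xist, transcribed from the inactive X chromosome, was well above background on Nod1 +/- replicates 1 and 3 and Nod1 -/- replicate 1, while the Y-linked Eif2s3y and Ddx3y were so on the other 3 arrays. None of the 4 sex-linked genes tested passed the threshold between genotypes. Their spread within both genotypes was wide (standard error 2.95 for Xist), so this does not show that sex was balanced.

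The comparison asked which transcripts of the fetal aorta differ with a working Nod1 allele 6 h after the ligand. In Nod1 +/- vessels the lists of chemokine, acute-phase and NF-kB feedback genes were shifted upward, with medians of 3.38, 2.27 and 1.69 on the log2 scale by camera's preset correlation (adjusted p = 0.106, 0.158 and 0.13 with an estimated correlation). The largest measured difference was in Saa3, an acute-phase serum amyloid A (chromosome 7, 53970389 to 53970448), at 5.91 ± 0.83 against -2.60 ± 0.93, a 366-fold difference (log2 8.51, standard error 0.58; adjusted p = 0.00111). Sele, the endothelial selectin that captures rolling leukocytes (chromosome 1, 165987726 to 165987785), was at least 26.7-fold higher (adjusted p = 0.000243). The naming rule, which ranks measured differences, also took Ccl5, Cxcl10, Ccl2, Irg1, Slfn4, Gpr84, Serpina3n and Mt2. Irg1, whose enzyme makes itaconate in activated myeloid cells, was at least 17.4-fold higher (adjusted p = 0.000882). Slfn4, a Schlafen gene of myeloid cells, rose 47.0-fold (log2 5.55; adjusted p = 0.00261), although it was well above background on 1 of the 3 Nod1 -/- arrays. Gpr84, a medium-chain fatty acid receptor of myeloid cells, rose 46.9-fold (log2 5.55; adjusted p = 0.000577) and was well above background on 2 of those arrays.

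In all, 4012 of 21478 genes changed (18.7%), 1646 of them higher and 2366 lower in Nod1 +/- aortas. The high end was far longer than the low end, with 81 changed genes at least 8-fold higher and 2 at least 8-fold lower when dim genes were set at their bound. At a 2-fold minimum, 632 were higher and 571 lower by measured difference, or 631 and 498 with dim genes at their bound. The median difference of all genes was -0.10, and 0.01 after median scaling, which left 2506 changed genes, 1580 higher and 926 lower. The count fell to 1636 without a filter on dim probes, to 2284 with Xist signal as a covariate, and to 1033 with the slide row as a block, which sets the Nod1 +/- arrays against Nod1 -/- replicate 3 alone. It was 2147 or 2085 without Nod1 +/- replicate 1 or 2, 1856 or 1460 without Nod1 -/- replicate 1 or 2, and 631 without both first replicates, a pair chosen for its muscle and nerve transcripts after the data were seen. The slide row as a block ended the calls of 49 of 121 changed genes picked out by name, among them Flt1, Fabp7, Gp1ba, Grhl3, Lum, Ogn, Mfap2, Kif20a, Car9, Hk2, Pfkfb3, Ctgf, Maff and F3 (adjusted p between 0.0542 and 0.115).

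**Figure D1:**
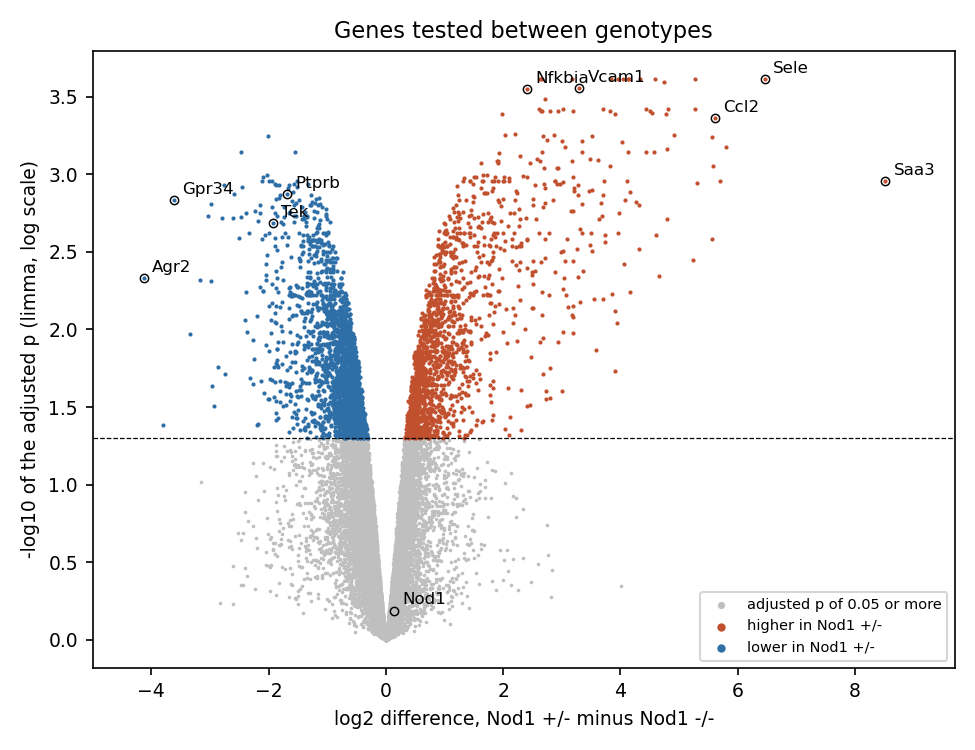
Each point is 1 of the 21478 tested genes, with the log2 difference Nod1 +/- minus Nod1 -/- on the horizontal axis and -log10 of limma's adjusted p on the vertical axis. Saa3 lies farthest to the right at 8.51 and Agr2 farthest to the left at -4.13, while Nod1 lies at 0.13.

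Of 26 measured chemokine genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone), with a median difference of 3.38, or 3.02 with dim members at their bound (camera adjusted p = 1.3e-15; adjusted p = 0.106 with an estimated correlation). Ccl2, which draws monocytes, rose 49.0-fold (log2 5.61, standard error 0.28; adjusted p = 0.000435). Ccl5, which attracts T cells and monocytes, rose 56.0-fold, and Cxcl10, an interferon-inducible ligand of CXCR3, rose 52.0-fold (adjusted p = 0.000667 and 0.00111). A second, dimmer Cxcl10 probe rose less, by 2.66 on the log2 scale against 5.70 for the probe used. Ccl19 (3.85) and the membrane-bound chemokines Cx3cl1 (4.33) and Cxcl16 (2.62) also rose. The member that fell was the B-cell chemokine Cxcl13 (-0.82; adjusted p = 0.0126), picked out after its values were seen. The call of Cxcl13 was lost without Nod1 -/- replicate 1 (0.0503) or 2 (0.056), with median scaling (0.053), with the slide row as a block (0.115) and without both first replicates (0.135).

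Genes of endothelial activation moved both ways. Of 20 measured endothelial activation genes, 10 rose and 3 fell (11 and 6 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.00011; adjusted p = 0.205 with an estimated correlation). Besides Sele, P-selectin (Selp) rose 28.2-fold, Icam1 16.4-fold and Vcam1 9.83-fold (log2 4.82, 4.04 and 3.30; adjusted p = 0.000382, 0.000243 and 0.000279). The 3 that fell, named after their values were seen, were tissue factor (F3, -0.84; adjusted p = 0.0133), thrombomodulin (Thbd, -0.52; adjusted p = 0.0173) and Icam2 (-0.53; adjusted p = 0.0224). Thbd and Icam2 passed the threshold neither without Nod1 +/- replicate 1 or 2 nor without Nod1 -/- replicate 1 or 2, with adjusted p between 0.0559 and 0.0673 for Thbd and between 0.0729 and 0.0855 for Icam2. Over all settings tried they reached 0.191 and 0.216.

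Genes induced by NF-kB, among them its own inhibitors, rose almost as a block. Of 30 measured, 25 rose and none fell (28 and 0 adjusted over the list alone), with a median of 1.69 (camera adjusted p = 6.73e-25; adjusted p = 0.13 with an estimated correlation). Nfkbia, encoding IkB-alpha, rose 5.29-fold (log2 2.40; adjusted p = 0.000284), the NF-kB subunit gene Nfkb2 6.52-fold, the anti-apoptotic Bcl2a1d 15.6-fold and Tnfaip2 17.6-fold. In the NOD pathway list, 8 of 22 measured genes rose and 1 fell, the same counts when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 6.05e-06; adjusted p = 0.158 with an estimated correlation). They included Nod2, the muramyl dipeptide sensor (3.90, well above background on 2 of the 3 Nod1 -/- arrays), the ubiquitin-editing enzyme gene Tnfaip3 (2.87), the endosomal peptide transporter gene Slc15a3 (3.48) and Birc3 (2.46). The member that fell was Xiap (-0.44; adjusted p = 0.0499), named after its values were seen. Its adjusted p lay between 0.0768 and 0.142 without Nod1 +/- replicate 1, 2 or 3 or Nod1 -/- replicate 1 or 2, and reached 0.32 with the slide row as a block.

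Of 19 measured cytokine and cytokine receptor genes, 12 rose and 1 fell, the same counts when adjusted over the list alone, with a median of 1.11 (camera adjusted p = 1.21e-08; adjusted p = 0.196 with an estimated correlation). Il1b was at least 8.94-fold higher in Nod1 +/- aortas (adjusted p = 0.000391). The macrophage growth factor Csf1 rose 4.28-fold, the B-cell survival factor Tnfsf13b 5.28-fold, and Osmr, a receptor subunit for oncostatin M, 2.71-fold. The other kept Csf1 probes rose less, by 1.14 and 1.15 on the log2 scale against 2.10 for the probe used. Il18 fell by 1.19 (adjusted p = 0.0201), as seen after the fact, with adjusted p = 0.0627 without Nod1 +/- replicate 1, 0.0518 without Nod1 +/- replicate 3, 0.0803 without Nod1 -/- replicate 2, 0.059 without a filter on dim probes, 0.109 with the slide row as a block and 0.128 without both first replicates.

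Acute-phase genes rose broadly, 21 of 26 measured with none lower (21 and 0 adjusted over the list alone), with a median of 2.27 (camera adjusted p = 2.32e-19; adjusted p = 0.158 with an estimated correlation). Beside Saa3 and the protease inhibitor gene Serpina3n (39.7-fold, log2 5.31; adjusted p = 0.00113), its relative Serpina3g rose 24.1-fold (adjusted p = 0.000243), the pentraxin gene Ptx3 8.05-fold and S100a9, a subunit of calprotectin, 9.03-fold. Glucocorticoid-responsive genes shifted upward as well. Of 15 measured, 6 rose and none fell (7 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 4.39e-06; adjusted p = 0.106 with an estimated correlation). On the log2 scale the metallothionein gene Mt2 rose by 5.28 (adjusted p = 0.000382), the siderophore-binding Lcn2 by 3.46, the metallothionein gene Mt1 by 2.75 and the cell-cycle inhibitor gene Cdkn1a by 1.43. A second Cdkn1a probe, at 0.41, did not pass (limma's adjusted p over all kept probes = 0.112). Several of these genes also answer to NF-kB, STAT3 or zinc.

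**Figure D2:**
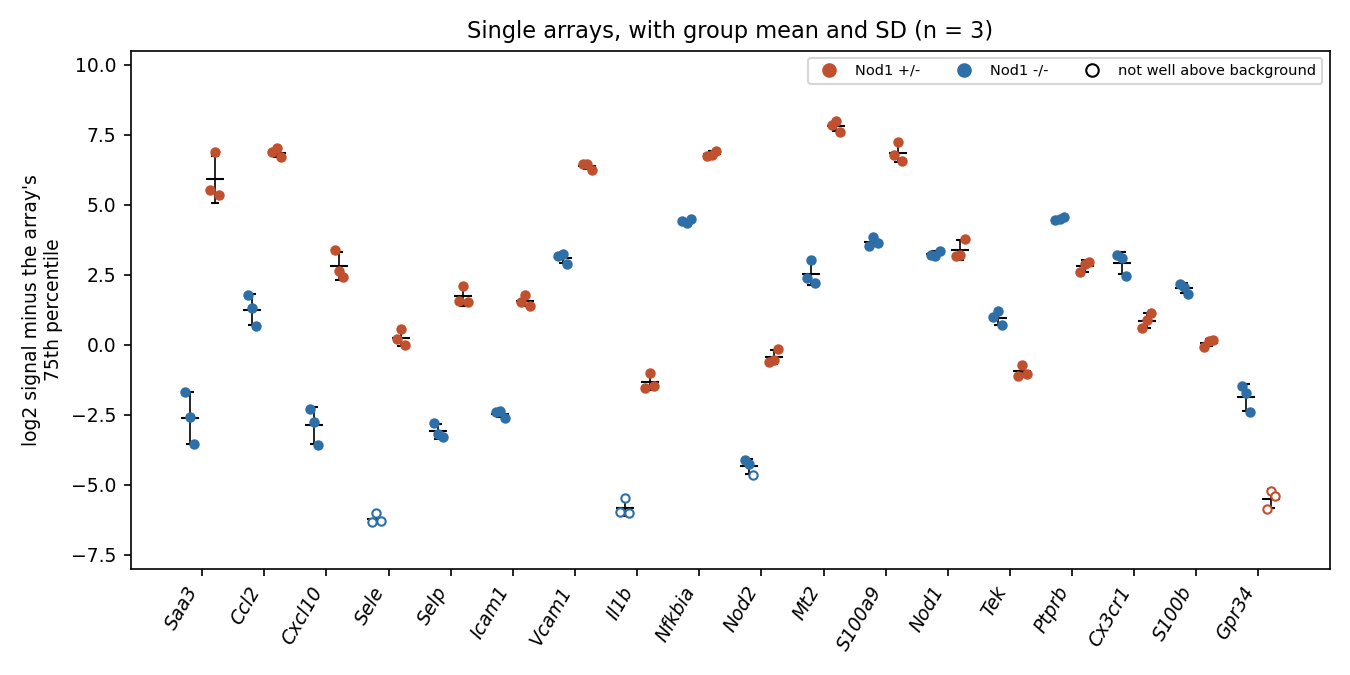
Points are single arrays, with log2 signal minus the array's 75th percentile on the vertical axis and the group mean with SD (n = 3) beside them, for genes named in the text. Saa3 lay at 5.91 in Nod1 +/- and -2.60 in Nod1 -/- aortas, and Nod1 at 3.38 and 3.25.

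Of 36 measured interferon-response genes, 9 rose and none fell, and 18 rose when adjusted over the list alone, with a median of 0.92 (camera adjusted p = 8.13e-10; adjusted p = 0.497 with an estimated correlation, and 0.0879 with fry). The guanylate-binding protein genes Gbp2 (13.1-fold), Gbp3 (4.90-fold) and Gbp4 (4.60-fold) and the transcription factor gene Irf1 (3.20-fold) rose. Immediate-early genes, transcription factors and their kin induced within minutes to hours of a stimulus, shifted as a group. Of 21 measured, 14 rose and none fell (15 and 0 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 2.87e-10; adjusted p = 0.158 with an estimated correlation). Examples were Fosl2 (1.51), Maff (1.09), Ctgf (0.93) and Btg2 (0.83).

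Transcripts typical of neutrophils were higher as well. Of 22 measured, 13 rose and none fell (14 and 1 adjusted over the list alone), with a median of 2.57, or 2.49 with dim members at their bound (camera adjusted p = 2.09e-11; adjusted p = 0.158 with an estimated correlation). Retnlg, a resistin-like gene of neutrophils, rose 14.1-fold, the cystatin-like Stfa2 10.2-fold and Stfa1 7.85-fold. Genes of this list that stood in the acute-phase list too were Lcn2, S100a8 and S100a9. Averaged over the list, Nod1 +/- replicates 1 to 3 lay at 1.92, 2.01 and 1.43, and Nod1 -/- replicates 1 to 3 at -0.35, -0.22 and -0.07. Red-cell genes did not share this difference: none of 14 changed, with a median of -0.40 (camera adjusted p = 0.214, and 0.0372, downward, without a filter on dim probes). Of 12 platelet and coagulation genes, 1 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.113). The platelet chemokine Ppbp rose 5.30-fold, while the platelet receptor subunit Gp1ba fell by 1.94 on the log2 scale. This list passed the threshold downward without Nod1 +/- replicate 2 (median -0.74; adjusted p = 0.0438), with median scaling (0.0431), without a filter on dim probes (0.016) and with fry (0.0223). Macrophage genes did not follow the neutrophil genes. Of 22, none rose and 4 fell, in the count adjusted over the list alone too, with a median of -0.34 (camera adjusted p = 0.38), and the fractalkine receptor gene Cx3cr1 fell by 2.05 (adjusted p = 0.00446). Without Nod1 -/- replicate 3 the macrophage list shifted downward, with a median of -0.57 and adjusted p = 0.00814, and without Nod1 -/- replicate 1 its median was -0.10. With the slide row as a block its median was 0.24 (adjusted p = 0.0905).

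**Figure D3:**
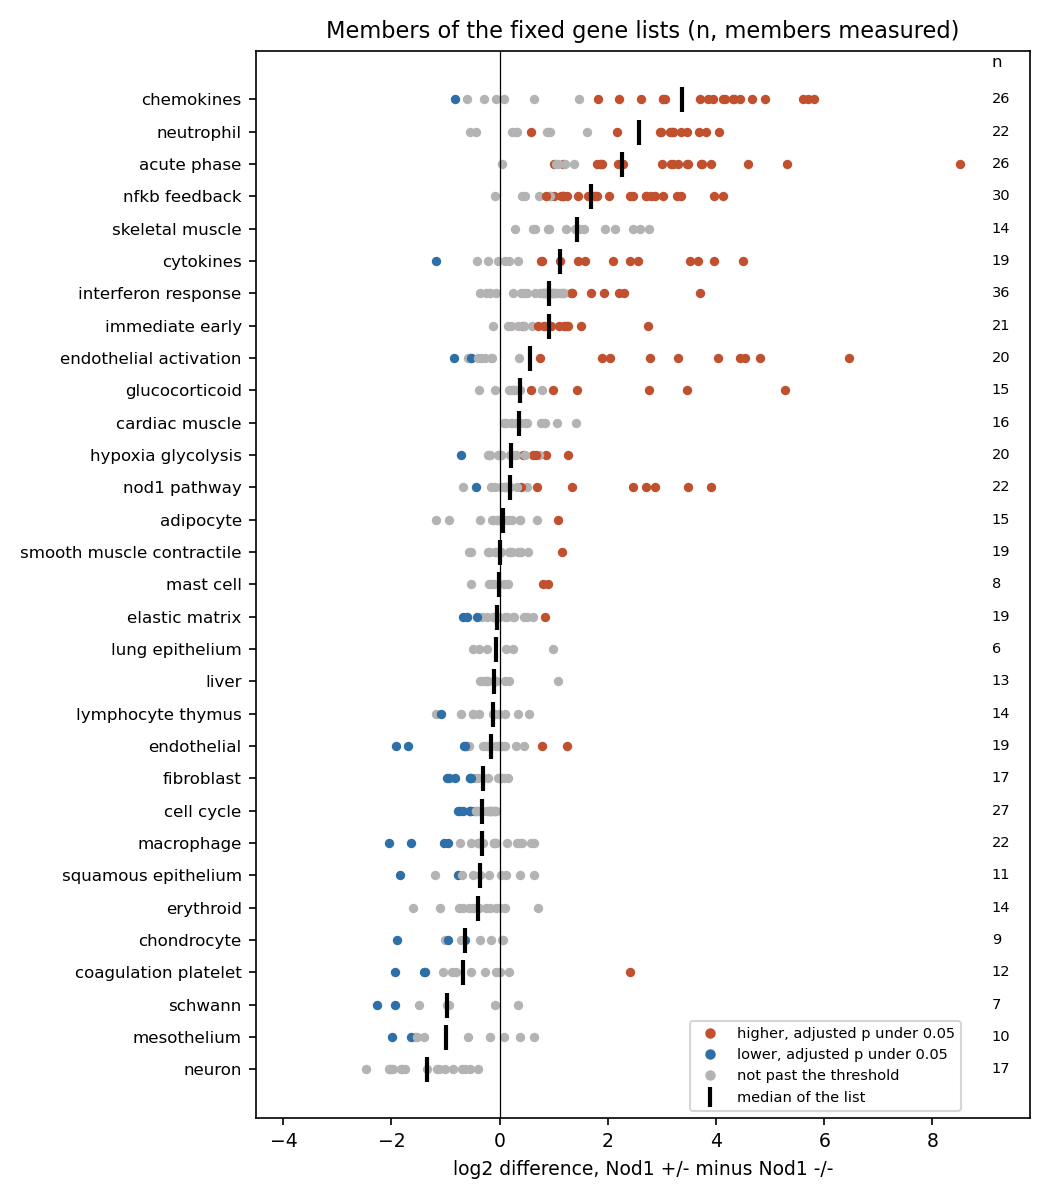
Each point is a measured member of a fixed gene list, placed by its log2 difference Nod1 +/- minus Nod1 -/-, coloured by its call over all genes, with a bar at the list's median and the number of members at the right. Chemokine genes had a median of 3.38 and red-cell genes (erythroid) a median of -0.40.

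The naming rule took 8 genes that were lower in Nod1 +/- aortas by measured difference, and 6 of them were not well above background on any Nod1 +/- array, so their order is not settled. Agr2, a protein disulfide isomerase of secretory epithelia (chromosome 12, 36730506 to 36730565), fell by 4.13 (standard error 0.49; adjusted p = 0.00467), although it was well above background on 1 of the 3 Nod1 +/- arrays. Gpr34, a lysophosphatidylserine receptor of macrophages and microglia, was dim in this way and at least 5.01-fold lower (adjusted p = 0.00147). In the same way, the tyrosine phosphatase gene Ptprr was at least 5.70-fold lower, the urea transporter gene Slc14a1 5.49-fold, Prrt4 4.76-fold, the adrenergic receptor gene Adra2c 3.81-fold and the choline phosphodiesterase gene Enpp6 2.20-fold. The neural crest transcription factor gene Tfap2b fell by 3.80 (adjusted p = 0.041) and was well above background on 1 of the 3 Nod1 +/- arrays. Without Nod1 +/- replicate 1 or 3 its difference was -4.87 or -3.16, and its adjusted p lay between 0.088 and 0.116 without Nod1 +/- replicate 2 or 3 or any single Nod1 -/- replicate. With the slide row as a block Tfap2b, Agr2, Adra2c and Prrt4 had adjusted p = 0.224, 0.0582, 0.106 and 0.0504, and without both first replicates Agr2 and Ptprr had 0.06 and 0.0615.

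Among genes that mark the vessel wall, the endothelial list moved both ways. Of 19, 2 rose and 5 fell (4 and 6 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.615). The VEGF receptor gene Flt1 rose 2.38-fold (adjusted p = 0.00725), whereas the angiopoietin receptor gene Tek fell by 1.92 (adjusted p = 0.00206) and the endothelial phosphatase gene Ptprb by 1.69 (adjusted p = 0.00135). The other member that rose was the guidance receptor gene Robo4 (0.79; adjusted p = 0.0263), with adjusted p between 0.0576 and 0.0971 without Nod1 +/- replicate 1 or 3 or Nod1 -/- replicate 2 or 3. None of 19 smooth-muscle contractile genes fell and 1 rose, with 0 adjusted over the list alone and a median of 0.00 (camera adjusted p = 0.458). This was Des, encoding desmin (1.15; adjusted p = 0.0335), with adjusted p between 0.076 and 0.11 without Nod1 +/- replicate 1 or 2 or Nod1 -/- replicate 1 or 2, and up to 0.246 over all settings tried. Of 19 elastic matrix genes, 1 rose and 3 fell, in both counts, with a median of -0.05 (camera adjusted p = 0.753, with its direction upward). Mfap2 and Fbln5, encoding proteins of elastic fibres, fell by 0.68 and 0.61.

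Fibroblast and dividing-cell genes lay slightly lower. Of 17 fibroblast genes, 6 fell and none rose, in both counts, with a median of -0.31 (camera adjusted p = 0.0436; adjusted p = 0.497 with an estimated correlation). The small proteoglycan genes Ogn and Lum fell by 0.98 and 0.95. This list no longer passed with quantile or median scaling (adjusted p = 0.0994 and 0.0754), with the slide row as a block (0.107), with the deposited table (0.103), or without Nod1 +/- replicate 1 (0.0927), Nod1 +/- replicate 3 (0.0875) or Nod1 -/- replicate 1 (0.0891), nor without both first replicates (0.184). All 27 cell-cycle genes had negative differences and 7 fell (8 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.000255; adjusted p = 0.497 with an estimated correlation), for example the mitotic kinesin gene Kif20a (-0.73; adjusted p = 0.0094, and 0.0535 with median scaling). Of 20 hypoxia and glycolysis genes, 5 rose and 1 fell, in both counts, with a median of 0.21 (camera adjusted p = 0.0104; adjusted p = 0.497 with an estimated correlation). Hexokinase 2 (Hk2, 1.27) and Pfkfb3 (0.68) rose, and the hypoxia marker Car9 fell by 0.71. The hypoxia list's adjusted p was 0.0692 without Nod1 +/- replicate 1, 0.0738 without both first replicates and 0.0879 with fry.

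Markers of tissues next to the aorta differed between arrays as well as between genotypes. Skeletal-muscle genes averaged 3.89 on Nod1 +/- replicate 1 and between -0.45 and 0.34 on the other 5 arrays. All 14 had positive differences and none changed singly, with a median of 1.44 (camera adjusted p = 0.00976; adjusted p = 0.738 with an estimated correlation). Without Nod1 +/- replicate 1 that median was 0.11 (adjusted p = 0.295). Cardiac genes had a median of 0.35 with none of 16 changed (camera adjusted p = 0.0119; adjusted p = 0.746 with an estimated correlation), and adjusted p = 0.0692 without Nod1 +/- replicate 1 and 0.222 without Nod1 -/- replicate 1. The cardiac median ran from 0.07 to 0.58 without single arrays. Neuronal genes averaged 2.19 on Nod1 -/- replicate 1, 0.49 and -0.51 on Nod1 -/- replicates 2 and 3, and 0.45, -1.03 and -1.43 on Nod1 +/- replicates 1 to 3, so the genotypes overlapped. None of the 17 changed singly, and their median was -1.35 (camera adjusted p = 0.0357; adjusted p = 0.784 with an estimated correlation). Without single arrays that median ran from -2.11 to -0.67. The neuronal list's adjusted p was 0.0711 without Nod1 +/- replicate 2, 0.244 without Nod1 +/- replicate 3 and 0.225 without Nod1 -/- replicate 1. With the slide row as a block the skeletal-muscle, cardiac and neuronal lists had adjusted p = 0.101, 0.841 and 0.91, and with fry 0.405, 0.442 and 0.26. Without both first replicates the skeletal-muscle and cardiac medians were -0.11 (adjusted p = 0.756 and 0.677), although camera's direction stayed upward.

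Glial and cartilage genes were lower in Nod1 +/- aortas. Of 7 Schwann-cell genes, 2 fell (5 adjusted over the list alone) and none rose, with a median of -0.97 (camera adjusted p = 0.0436; adjusted p = 0.497 with an estimated correlation). They were the calcium-binding S100b (-1.94; adjusted p = 0.00111) and the fatty acid-binding Fabp7 (-2.26; adjusted p = 0.0116). Without Nod1 +/- replicate 3 this list had adjusted p = 0.141, and without a filter on dim probes 0.161. Of 9 chondrocyte genes, 3 fell (5 adjusted over the list alone) and none rose, with a median of -0.65 (camera adjusted p = 0.037; adjusted p = 0.447 with an estimated correlation), among them the cartilage link protein gene Hapln1 (-1.90). Its adjusted p was 0.059 without a filter on dim probes, 0.097 without Nod1 +/- replicate 1, 0.0995 without Nod1 -/- replicate 3 and 0.0621 without both first replicates.

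The remaining lists did not pass the threshold. Mesothelial genes had a median of -0.995 with 2 of 10 lower (camera adjusted p = 0.291), and without Nod1 +/- replicate 2 a median of -1.52 and adjusted p = 0.000441. Squamous epithelial genes had a median of -0.36 with 2 of 11 lower (adjusted p = 0.407; 0.0466 without Nod1 +/- replicate 2), among them the epidermal transcription factor gene Grhl3 (-1.85). Lymphocyte and thymus genes had a median of -0.12 with 1 of 14 lower (adjusted p = 0.651), the B-cell receptor gene Cd79b at -1.09, and mast-cell genes a median of -0.01 with 2 of 8 higher (adjusted p = 0.291), Kit at 0.89 and Hdc at 0.80. Adjusted over the list alone, none of the lymphocyte genes and the same 2 mast-cell genes passed. Cd79b, at adjusted p = 0.0488 with all arrays, among the fits without a single array passed only without Nod1 -/- replicate 3 (adjusted p between 0.0781 and 0.118 without each other array), and reached 0.328 with the slide row as a block. Kit had adjusted p = 0.0534 without Nod1 -/- replicate 2 and 0.0799 without both first replicates, and Hdc between 0.0609 and 0.109 without any array but Nod1 -/- replicate 1. Adipocyte genes had a median of 0.06 (adjusted p = 0.445), lung epithelial genes of -0.06 (adjusted p = 0.579) and liver genes of -0.10 (adjusted p = 0.813, with camera's direction upward, and downward with a median of -1.25 and adjusted p = 0.011 without both first replicates). Of these 3 lists 1 gene changed, Dio2, a thyroid hormone-activating deiodinase (1.07; adjusted p = 0.0464), which among the fits without a single array kept its call only without Nod1 -/- replicate 2, with adjusted p up to 0.221 over all settings tried.

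**Figure D4:**
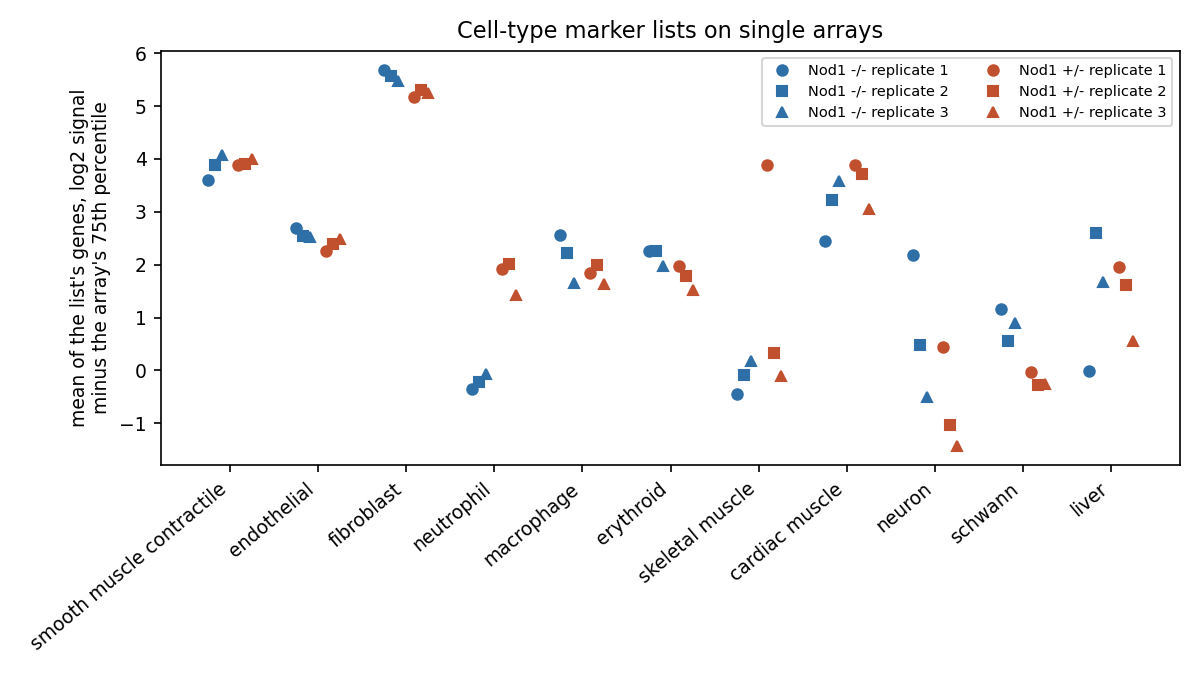
Points are single arrays, with the mean log2 signal minus the array's 75th percentile over the genes of each cell-type marker list on the vertical axis. Nod1 +/- replicate 1 stands at 3.89 for skeletal-muscle genes and Nod1 -/- replicate 1 at 2.19 for neuronal genes.

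Of 21 genes listed as neighbours of Nod1, 1 rose and 7 fell (1 and 9 adjusted over the list alone), with a median of -0.14. Set against all other genes by camera, the list had adjusted p = 0.12, equal to its unadjusted value because no other check list was large enough to test. With fry, which asks whether the list's genes move 1 way on balance and not whether they differ from other genes, adjusted p = 0.00311. The greatest fall was in Scrn1, which encodes secernin 1, by 1.87 (standard error 0.14; adjusted p = 0.00143), followed by Inmt (-1.50; adjusted p = 0.0061) and Chn2 (-1.17; adjusted p = 0.00264).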

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

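The fit without both first replicates was chosen after the data were seen, and all other settings were planned. No shifted list turned camera direction and no named gene past the threshold turned direction in any setting, though the cardiac list's median was -0.12 with the slide row. Of 121 such genes, none lost its call with normexp or a trend and robust prior, 1 with array weights, 2 with quantile scaling, 3 with the deposited table, 15 with Xist signal as a covariate, 20 with median scaling, 26 with no filter on dim probes, 49 with the slide row as a block and 51 without both first replicates. The counts of changed, higher and lower genes (4012, 1646 and 2366) moved to 1636, 802 and 834 with no filter, where more genes were tested, to 1203, 632 and 571 at a 2-fold minimum, to 2284, 1029 and 1255 with Xist, to 1033, 606 and 427 with the slide row and to 631, 403 and 228 without both first replicates, the last 3 with fewer degrees of freedom. Median scaling gave 2506 changed, 1580 of them higher and 926 lower, and moved the median of all genes from -0.10 to 0.01. Why the count fell was not tested. Array weights gave 3803 lower genes, and the cause was not tested. Quantile scaling and the deposited table gave 4066 and 4035 changed genes, both with a median of -0.062 for all genes. They are therefore not separate checks. Leaving out single arrays gave 1460 to 3382 changed, 739 to 1285 higher and 721 to 2097 lower genes, with fewer arrays. The 18 shifted lists became 0 with an estimated correlation, 14 with fry, 16 with the slide row and 13 to 20 without single arrays. Whether the replicate numbers pair the samples stays open. Arrays with the same number had correlations of 0.083, 0.277 and 0.111 of their deviations, and those with different numbers between -0.306 and 0.126. Nod1 +/- replicates 1 and 2 correlated best with the array of the same number. Nod1 +/- replicate 3 did so with Nod1 -/- replicate 1 (0.126). With the number as a block 4040 genes changed and 15 lists shifted, without the fibroblast, Schwann and chondrocyte lists. Nod1 lay between -0.07 (without Nod1 +/- replicate 3) and 0.24 without single arrays, and at 0.02 with the slide row. Lists not called in the first place changed camera direction, and the cause was not tested. Their medians were, with the slide row, -0.10 for smooth muscle, -0.16 for elastic matrix, 0.24 for macrophage, -0.14 for lymphocyte, -0.59 for lung and -0.36 for liver genes; with fry or no filter, -0.054 for elastic matrix and -0.10 for liver; with median scaling, 0.007 for liver; and without both first replicates, -0.087 for endothelial, 0.10 for adipocyte, -0.23 for lung and -1.25 for liver genes (adjusted p = 0.011). Without single arrays these medians ran from -0.12 to 0.13 for smooth muscle, -0.13 to 0.049 for elastic matrix, -0.57 to -0.10 for macrophage, -0.29 to 0.18 for mast-cell, -0.31 to 0.32 for adipocyte and -0.88 to 0.55 for liver genes. Signal over background limits 47 higher genes that were not well above it on any Nod1 -/- array and 139 lower genes that were not on any Nod1 +/- array. Their measured differences are not bounds, and the bounds given as folds are smaller (for Sele 4.74 on the log2 scale against a measured 6.46). Normexp with its offset shrinks the measured differences by construction (Sele from 6.46 to 3.09).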

Other observations

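The tests of blood, of macrophage number, of scaling and of a cis difference at Scrn1 were chosen only after the results were seen, as were the gene families of the next 2 paragraphs, and the other tests beforehand. Of 19 MHC class I genes, 9 rose and none fell, around a median of 0.90 (camera adjusted p = 1.2e-06 over 18 families; adjusted p = 0.474 with an estimated correlation), among them H2-K1, at a mean of 5.42 in Nod1 +/- and 3.42 in Nod1 -/- aortas (adjusted p = 0.0024), and H2-Q7, up by 1.54 on the log2 scale. Of 8 class II genes 1 rose, around a median of 0.05 (adjusted p = 0.276). Of 41 proteasome genes 7 rose and none fell, around a median of 0.03 (adjusted p = 0.0159; adjusted p = 0.867 with an estimated correlation). They included the immunoproteasome subunits Psmb8 (1.93) and Psmb10 (1.85) and the activator Psme2 (0.87). The proteasome call was lost without Nod1 +/- replicate 1 (0.0578), Nod1 +/- replicate 2 (0.0526) and Nod1 -/- replicate 3 (0.308), without a filter on dim probes (0.0859) and with fry (0.211). The proteasome median was -0.007 without Nod1 +/- replicate 2 and -0.058 without Nod1 -/- replicate 3. Casp4, the receptor of cytosolic lipopolysaccharide in the non-canonical inflammasome, rose by 3.20.

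The Serpina3 cluster rose in 6 of 9 measured genes with none lower (median 2.67; adjusted p = 1.52e-06; adjusted p = 0.273 with an estimated correlation), Serpina3h among them at 2.67. Among 22 metallothionein and zinc transporter genes 6 rose and 1 fell (adjusted p = 0.00514; adjusted p = 0.474 with an estimated correlation), and the zinc transporter gene Slc30a8, best known from pancreatic islets, was at least 13.3-fold higher. Of 16 Notch pathway genes, 4 fell and none rose, around a median of -0.39 (adjusted p = 0.0462; adjusted p = 0.654 with an estimated correlation), and the Notch targets Hey1 (-1.57), Hey2 (-1.22) and Heyl (-1.30) were among them. The Notch call was lost without Nod1 +/- replicate 1 (0.0606), Nod1 -/- replicate 3 (0.111) or both first replicates (0.0788), and with probes well above background on all 6 arrays (0.0611). Ribosomal protein genes (median -0.16) and oxidative phosphorylation genes (median -0.20) were also called downward (adjusted p = 0.00395 and 0.00552; adjusted p = 0.654 and 0.884 with an estimated correlation), beside a median of -0.10 for all genes. The ribosomal call was lost with median scaling (median -0.05; 0.213), quantile scaling (0.385), the deposited table (0.381) and the slide row as a block (0.0806). The oxidative phosphorylation call was lost with median scaling (median -0.10; 0.0541), the slide row (0.241) and fry (0.209), and without Nod1 +/- replicate 3 or Nod1 -/- replicate 2 it had adjusted p = 0.348 or 0.0558.

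The split of the 6 arrays by genotype gave 4012 changed genes, and the highest of the other splits gave 7. It was 1 of 10 splits, too few for a share under 0.05.

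Neutrophil transcripts were higher in Nod1 +/- aortas 6 h after the ligand. More blood in those vessels would raise red-cell genes too, but the erythroid list had a median of -0.399 (95% bootstrap interval -0.66 to -0.079) against 2.568 (0.882 to 3.206) for the neutrophil list. The bootstrap intervals here and below resampled the genes of a list, not the arrays. Neutrophils may be the source, since a second neutrophil list had a median of 2.037 (-0.031 to 3.188), with 6 of 10 genes higher, exactly the 60% set as the limit. Such a list cannot tell neutrophils in the vessel wall from neutrophils in blood left in the vessel. Padi4, Fpr2 and Clec4d rose by 1.79, 3.09 and 3.19, while Pygl of the same list fell by 0.51 (adjusted p = 0.0231), and Cd300lf (-0.29), Slc2a3 (-0.03) and Alox5ap (0.23) did not pass the threshold. Induction of these genes in other cells stays open, and without arrays from untreated dams a response to FK565 was not separated from a difference between genotypes at rest.

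Of the macrophage list 4 genes fell, while the whole list was not called, and Gpr34, outside the list, was at least 5.01-fold lower. Ly86, Lyve1 and Csf1r lost their calls in 5, 8 and 11 of 20 settings, and Cx3cr1 in none. The other kept Csf1r probes did not pass (-0.734 and -0.309, limma's adjusted p over all kept probes = 0.169 and 0.14). The list's median was -0.335 (-0.41 to -0.065), beside -0.10 for all genes, and it shifted downward without Nod1 -/- replicate 3 (adjusted p = 0.00814), so fewer macrophages in Nod1 +/- aortas may or may not account for the falls. The choice among the scalings tried was not the whole cause for Cx3cr1, Ly86 and Lyve1. These genes stayed past the threshold with quantile and median scaling and in the deposited table, with a smallest fall of -0.927. Those settings moved the median of all genes only from -0.10 to -0.062 or 0.01, so they could test only small shifts. For Csf1r the part of scaling stays undecided. Median scaling moved its difference from -0.96 (standard error 0.21; adjusted p = 0.0295) to -0.851 (standard error 0.25; adjusted p = 0.072), a slightly smaller fall with a wider error. With the slide row as a block only Cx3cr1 of these passed (-1.59; adjusted p = 0.0315). A change of state of the macrophages, or a loss of 1 subset, stays open too.

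Genes near Nod1 differed between genotypes. DNA of the targeted stem cells around the locus may differ from C57BL/6, yet 20.4% of 137 genes within 10 Mb of the Nod1 probe had changed against 18.7% of 21112 genes elsewhere (Fisher's exact p = 0.583), which decides nothing. A narrower window was not tested. Of the 21 listed neighbours 1 rose and 7 fell, all with probes starting between 54250225 (Chn2) and 55298480 (Aqp1), as seen after the fact. Znrf2, Plekha8, Gars, Prr15 and 2410066E13Rik (Mturn) lay in that span too and did not pass, nor did any listed neighbour outside it. Of the 28 changed genes within 10 Mb, 35.7% were higher in Nod1 +/-, with an upper bound of 55.9%, beside 41% of all changed genes. A share this near that of all changed genes cannot decide on probe binding, so weaker binding to stem-cell sequence was not excluded. For Scrn1, a difference in cis between linked alleles allows at most a fall by 1 if both parents' alleles are expressed and add up. The measured -1.865 (95% confidence interval -2.22 to -1.52) went beyond that limit. Expression by parent of origin was not tested, and with Nod1 -/- dams the intact allele always came from the father. A cis difference alone is therefore not excluded. A response downstream of Nod1, or a cis difference on top of one, stays open too.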
